A study of Gallus gallus with 9 samples.

How the data were processed

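RNA was measured in the liver of chickens at 3 ages, namely embryonic day 13, 5 weeks and 42 weeks after hatching. Each age had 3 libraries, which the labels call biological replicates, so 9 libraries were compared. Sex, flock, breed and sequencing batch are not given in the sources used here, and no batch could be separated from age. Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made with an Illumina TruSeq RNA kit from total RNA. Per the submitters' processing notes, HISAT, StringTie 1.3.3, Cufflinks 2.2.1 and DESeq2 were used, with no role or order stated. The aligner settings, genome build and annotation are not given in the sources used here.

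The authors deposited 1 table of protein-coding genes and 1 table of long non-coding RNAs (lncRNAs), both with log2 values of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The deposited log2 values were read as log2(FPKM + 1). In the mRNA table this offset follows from the values, since no back-transformed value lies between 0 and 0.1 FPKM and the smallest above 0 is 0.100. For the lncRNA table the same offset was assumed. The mRNA table lists 13949 genes, and 5041 of its 125541 values are exactly 0. Every gene in it is above 0 in at least 5 libraries. The lncRNA table lists 4127 lncRNAs, all above 0 in all 9 libraries. Features present at a single age can therefore be missing from either table, and an exact 0 in the mRNA table stands for a value below 0.1 FPKM rather than for absence.

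The tables hold no read counts, and the depth of each library is unknown. Low values were searched for a common step of 1 read. At most 6 of 137 low mRNAs and 3 of 71 low lncRNAs shared a ratio between libraries within 0.01 on the log2 scale, so no depth was recovered and no count model was used. All 9 columns of each table belong to these libraries, and 0 further columns were left aside.

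Genes carry Ensembl identifiers and lncRNAs carry transcript-unit identifiers, and the files do not pair them with names. Of these identifiers 0 matched the reference table of gene symbols. For this reason 26 gene lists and 15 anchor genes that had been fixed by symbol before the data were examined, together with their set tests, were not analysed here. Identifiers are printed as deposited, with no gene name, position or function.

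Tests were run on the deposited log2 scale with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per age was fitted to all 9 libraries, so that all ages share 1 estimate of the spread, and variances were moderated with a mean-variance trend. Genes entered the test with at least 1 FPKM in at least 3 libraries (11512 mRNAs), and lncRNAs with at least 0.5 FPKM in at least 3 libraries (2213 lncRNAs). P-values were two-sided and adjusted by Benjamini-Hochberg within each table and comparison. A feature was called higher or lower at an adjusted p under 0.05 and an absolute log2 difference of at least 1. A moderated F test over the 3 ages used the adjusted p alone. All adjusted p-values in the text are from limma. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of features with low FPKM. Differences given as 2-fold or 1.5-fold are on that scale too. Means and SDs of FPKM are over the 3 libraries of an age. A fold against an age listed at 0 is not given.

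The rule for named features, fixed before the data were examined, took the largest rises and falls among called features whose libraries did not overlap between the ages, with a mean of at least 10 FPKM for mRNAs or 1 FPKM for lncRNAs in the higher age. It was planned for 8 mRNAs and 3 lncRNAs per direction with a gene symbol for mRNAs. As no symbols could be matched, the first 2 per direction of each comparison and table are named. The same number is named among features highest or lowest at 5 weeks.

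Libraries were compared by Pearson correlation across features and by principal components. Because the median log2 difference between ages moved by more than 0.1 under scaling, every comparison was also made after shifting all libraries to the same median and after quantile normalization. Other alternatives were no filter and a stricter filter, a fit without the variance trend, a fit to the compared ages alone, the replicate number as a block, the adjusted p alone, a test against a 1.5-fold change, and leaving out each library in turn. An offset of 0.1 FPKM was added after the data were seen. A further setting chosen beforehand, log2(FPKM + 1), is identical to the deposited scale.

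The fit was tested on simulated data in which 200 features differed between 42 weeks and 5 weeks. Among 11512 simulated mRNAs, 95 of 100 with a log2 change of 1.5 and 100 of 100 with a log2 change of 3 were called, with 6 calls among 11312 unchanged ones. Among 2213 simulated lncRNAs the calls were 98 of 100 and 100 of 100, with 0 among 2013 unchanged ones. The simulated values were drawn from a normal distribution with the fitted spread, equal at every age. In the data the median SD of mRNAs was 0.29 at 42 weeks against 0.19 at 5 weeks. The rate of false calls between these ages is therefore not known from the simulation.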

Results

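The transcriptome of chicken liver was profiled before hatching, at embryonic day 13, and in birds aged 5 weeks or 42 weeks, with 3 libraries per age. The comparisons asked how protein-coding and long non-coding transcripts differ between these developmental stages. Expression was given as FPKM, with no read depth, so error was taken from the spread between the 3 libraries of an age. SEs and p-values pool that spread over all 3 ages, so they do not measure the spread of the compared ages alone.

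The 9 libraries separated by age in both tables. The first component held 66.7% of the mRNA variance and the second 19.5%, while for lncRNAs these shares were 49.6% and 20.3%. Within an age, Pearson's r across genes was 0.987 to 0.988 at embryonic day 13, 0.980 to 0.982 at 5 weeks and 0.950 to 0.981 at 42 weeks. Between ages it was 0.855 to 0.861 for day 13 and 5 weeks, 0.907 to 0.929 for 5 and 42 weeks, and 0.809 to 0.826 for day 13 and 42 weeks. For lncRNAs r was 0.900 to 0.908, 0.825 to 0.840 and 0.746 to 0.858 within the 3 ages, and 0.543 to 0.687 between ages. These correlations are across features, which are not independent replicates. The median SD of a gene between libraries of an age was 0.15 log2 units at day 13, 0.19 at 5 weeks and 0.29 at 42 weeks. The third 42-week library stood apart from the other two, with 1109 of 11512 genes at least 2-fold off their mean.

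**Figure D1:**
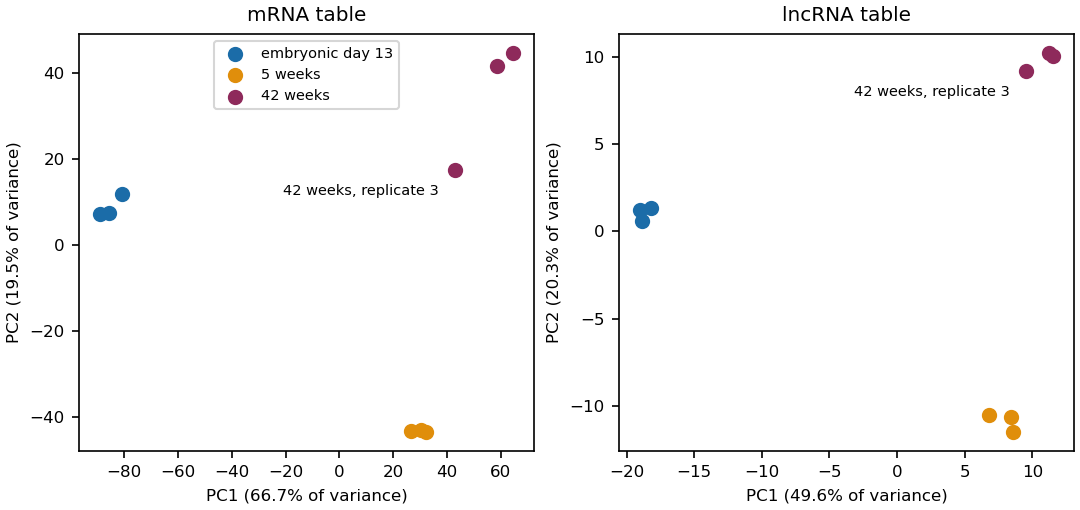
Principal components of the tested mRNAs (left) and lncRNAs (right) on the log2(FPKM + 1) scale, with 1 point per library coloured by age and the share of variance on each axis. The 3 ages lie apart in both panels, and replicate 3 at 42 weeks lies away from the other two libraries of its age in the mRNA panel.

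The most abundant transcripts took a larger share of the mRNA signal after hatching. The 20 most abundant genes of each library held 35.2% ± 1.6 of the summed FPKM at embryonic day 13, 43.7% ± 1.4 at 5 weeks and 45.7% ± 5.3 at 42 weeks (SD, n = 3 each). A mean of at least 1000 FPKM was reached by 55 genes at day 13, 53 at 5 weeks and 39 at 42 weeks, and 16 genes reached it at all 3 ages. Of the 91 genes that reached it at any age, 24 did so at day 13 alone, 16 at 5 weeks alone and 11 at 42 weeks alone. For lncRNAs the 10 most abundant held 19.4% ± 0.5 of the signal at day 13, 12.5% ± 1.4 at 5 weeks and 10.9% ± 1.3 at 42 weeks. A mean of at least 10 FPKM was reached by 32 lncRNAs at day 13, 18 at 5 weeks and 15 at 42 weeks. The median log2(FPKM + 1) of the listed mRNAs was 2.75 ± 0.08 at day 13, 2.27 ± 0.10 at 5 weeks and 2.18 ± 0.23 at 42 weeks.

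The comparison of 5 weeks with embryonic day 13 spans hatching. ENSGALG00000035803 was listed at 0 in all 3 embryonic libraries and had 427 ± 220 FPKM at 5 weeks (SD, n = 3; adjusted p = 1.0e-07). ENSGALG00000020388 rose from 2.14 ± 1.26 to 963 ± 489 FPKM, a log2 difference of 8.23 ± 0.48 (SE; adjusted p = 5.3e-07). In the other direction, ENSGALG00000004445 had 170 ± 24.8 FPKM at day 13 and was listed at 0, 0.145 and 0.148 FPKM in the 5-week libraries, a log2 difference of -7.27 ± 0.20 (adjusted p = 6.4e-09). ENSGALG00000030908 fell from 71.6 ± 3.92 to 0.208 ± 0.11 FPKM, a log2 difference of -5.91 ± 0.63 (adjusted p = 2.4e-05). In all, 822 mRNAs were higher and 2802 lower at 5 weeks, which is 31.5% of those tested. The genes called higher held 5.45% ± 0.20 of the summed FPKM at day 13 and 31.6% ± 2.6 at 5 weeks, and those called lower held 33.9% ± 1.1 and 10.4% ± 0.4. Here and below, the direction of such a change in share follows from the calls, which were made on the same libraries. Of all 11512 tested genes, called or not, 8239 had libraries that did not overlap between the 2 ages on the deposited scale, where chance gives 10% for a single gene. The count was not repeated under other scalings. A shift shared by all genes, whose median log2 difference was -0.46, also separates libraries, so the 10% is no reference for the total.

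The balance between rises and falls depended on scaling. The median log2 difference of all tested genes was -0.46, and 77.3% of the called genes were lower on the deposited scale. After median scaling 1498 were higher and 1269 lower (45.9% lower), and after quantile normalization 1270 and 1380 (52.1% lower). Under all 3 scalings 819 genes were called higher and 1260 lower, among them the 4 genes named for 5 weeks against day 13. Both other scalings move the mRNA differences upward, here and in the later comparisons, so rises mostly keep their calls by construction. Among the 50 genes with a mean of at least 1000 FPKM over the 9 libraries, 18 were higher and 10 lower, and 16 and 6 were so under all 3 scalings. Among the 6975 genes under 10 FPKM, 406 were higher and 1663 lower, and 405 and 716 under all 3 scalings.

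**Figure D2:**
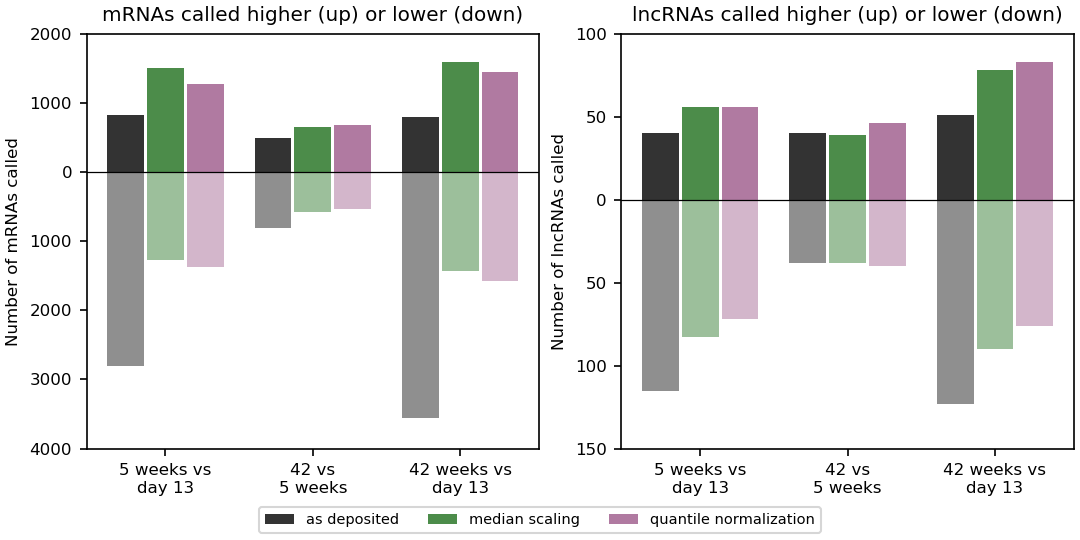
Number of mRNAs (left) and lncRNAs (right) called higher (bars above 0) or lower (paler bars below 0) in each comparison, for the deposited scale, median scaling and quantile normalization. For 5 weeks against day 13 the mRNAs called lower number 2802 as deposited, 1269 after median scaling and 1380 after quantile normalization.

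Among lncRNAs, TU63378 rose from 1.67 ± 0.23 FPKM at day 13 to 50.8 ± 18.9 at 5 weeks, a log2 difference of 4.21 ± 0.31 (adjusted p = 1.1e-05). TU64425 rose from 0.0442 ± 0.0431 to 18.2 ± 3.63 FPKM (log2 difference 4.18 ± 0.23, adjusted p = 1.1e-06). TU57895 fell from 90.7 ± 42.6 to 2.40 ± 2.22 FPKM (log2 difference -4.92 ± 0.56, adjusted p = 0.00021), and TU2690 fell from 23.8 ± 8.46 to 0.632 ± 0.439 FPKM (log2 difference -3.90 ± 0.32, adjusted p = 1.9e-05). The difference of TU57895 was -4.23 without the third 5-week library. In all 40 lncRNAs were higher and 115 lower, which is 7% of those tested. Of the called lncRNAs 74.2% were lower as deposited, 59.7% after median scaling and 56.2% after quantile normalization, and 39 were higher and 72 lower under all 3 scalings. The 115 called lower held 30.5% ± 0.5 of the summed lncRNA FPKM at day 13 and 6.65% ± 0.92 at 5 weeks.

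The comparison of 42 weeks with 5 weeks covers the later interval after hatching. ENSGALG00000001863, listed at 0 in all embryonic libraries, had 0.821 ± 0.371 FPKM at 5 weeks and 27210, 25000 and 7630 FPKM in the 42-week libraries (log2 difference 13.24 ± 0.40, adjusted p = 2.8e-08). ENSGALG00000042672 was listed at 0, 0.163 and 0.256 FPKM at 5 weeks and at 9245, 8346 and 2566 FPKM at 42 weeks (log2 difference 12.33 ± 0.39, adjusted p = 2.8e-08). ENSGALG00000007636 fell from 323 ± 203 to 1.77 ± 1.68 FPKM (log2 difference -6.76 ± 0.57, adjusted p = 4.7e-05), and ENSGALG00000007109 fell from 1378 ± 402 FPKM to 12.0, 27.02 and 191 FPKM in the 42-week libraries (log2 difference -5.02 ± 0.73, adjusted p = 0.00096). All 4 calls held without any single library, but the log2 differences moved. Without the third 42-week library that of ENSGALG00000001863 was 13.83, that of ENSGALG00000042672 12.92 and that of ENSGALG00000007109 -6.14, which was -4.19 without the first. Without the second 5-week library that of ENSGALG00000007636 was -7.48. A mean under 1 FPKM at 5 weeks was followed by at least 100 FPKM at 42 weeks in 7 genes, and by at least 1000 FPKM in 5 of these. In the reverse direction the number was 0. Genes above 0 at a single age are not among those listed, which limits both numbers.

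Between 5 and 42 weeks 497 mRNAs were higher and 806 lower, 11.3% of those tested. The genes called higher held 1.90% ± 0.18 of the summed FPKM at 5 weeks and 26.6% ± 12.4 at 42 weeks, and those called lower held 35.4% ± 3.2 and 11.6% ± 2.2. Much of the share of the higher genes came from few of them. ENSGALG00000015134 alone held 12.9% and 11.4% in the first and second 42-week libraries, and its FPKM was lower in the third. The median log2 difference of all tested genes was -0.17. Of the called genes 61.9% were lower as deposited, 46.8% after median scaling and 44.2% after quantile normalization, and 493 were higher and 485 lower under all 3 scalings, the 4 named genes included. A single library changed the count of falls, which was 1305 without the third 42-week library and 604 without the first. By level, 30 genes with 100 to 1000 FPKM were higher and 114 lower (30 and 64 under all 3 scalings), while of the 6975 under 10 FPKM 279 were higher and 272 lower (277 and 166 under all 3 scalings).

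For lncRNAs between 5 and 42 weeks, TU45477 rose from 0.353 ± 0.302 to 8.60 ± 1.57 FPKM (log2 difference 2.84 ± 0.21, adjusted p = 5.1e-05) and TU11915 from 2.59 ± 0.63 to 16.0 ± 6.68 FPKM (log2 difference 2.18 ± 0.27, adjusted p = 0.0013). TU17917 fell from 8.13 ± 4.62 to 0.894 ± 0.673 FPKM (log2 difference -2.22 ± 0.42, adjusted p = 0.0082). TU64731 had 85.5 ± 37.9 FPKM at 5 weeks and 15.1 ± 14.4 at 42 weeks (log2 difference -3.23 ± 0.91, adjusted p = 0.043). Its call was lost in 11 alternatives, with adjusted p-values of 0.051 to 0.12 there, median scaling and quantile normalization included. The size of its fall rested on the third 42-week library, which had 0.287 FPKM against 15.8 and 29.1 in the other two, and without that library the log2 difference was -1.86 (adjusted p = 0.020), while it was -4.13 without the second. Altogether 40 lncRNAs were higher and 38 lower, 3.5% of those tested, and 39 and 36 were so under all 3 scalings.

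Across the whole interval, ENSGALG00000015134 had the largest rise on the log2(FPKM + 1) scale among mRNAs named by the rule. It was listed at 0 in 2 of the 3 embryonic libraries, had 85.3 ± 106 FPKM at 5 weeks, and had 52140, 48680 and 10140 FPKM in the 42-week libraries (log2 difference from day 13 14.43 ± 0.90, adjusted p = 6.5e-07). ENSGALG00000001863 followed on that scale, listed at 0 at day 13 (adjusted p = 5.9e-09). With an offset of 0.1 FPKM the order was reversed, with log2 differences of 17.40 for ENSGALG00000001863 and 16.87 for ENSGALG00000015134. ENSGALG00000004445 fell by 7.21 ± 0.20 on the log2 scale (adjusted p = 5.9e-09). ENSGALG00000004230 fell from 1130 ± 211 FPKM at day 13 to 65.4 ± 31.6 at 5 weeks and 9.78 ± 8.99 at 42 weeks, a log2 difference between the end points of -7.16 ± 0.63 (adjusted p = 4.5e-06). That difference was -6.33 without the first 42-week library and -7.84 without the second, and that of ENSGALG00000015134 was 15.20 without the third. In all 790 mRNAs were higher and 3562 lower at 42 weeks than at day 13, 37.8% of those tested, with a median log2 difference of -0.61. The genes called higher went from 2.57% ± 0.13 to 36.6% ± 10.8 of the summed FPKM and those called lower from 55.1% ± 2.0 to 21.0% ± 3.3. Among the higher ones, ENSGALG00000015134 alone held 12.9% and 11.4% in the first and second 42-week libraries. Median scaling gave 1593 higher and 1426 lower and quantile normalization 1450 and 1578, so that 81.8% of the called genes were lower as deposited, 47.2% after median scaling and 52.1% after quantile normalization. Under all 3 scalings 790 were higher and 1417 lower, the 4 named genes included.

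**Figure D3:**
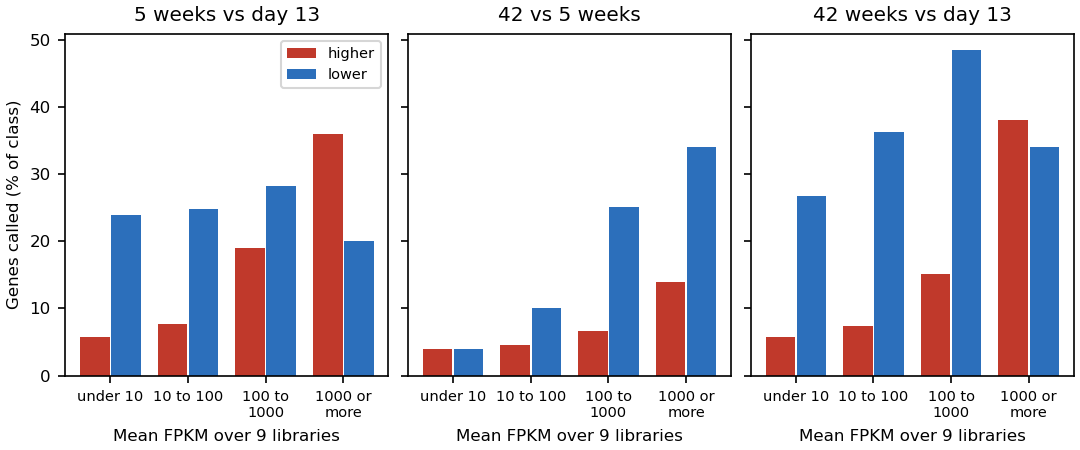
Share of tested mRNAs called higher (red) or lower (blue) on the deposited scale in each comparison, by class of mean FPKM over the 9 libraries. From day 13 to 42 weeks, 63.7% of the genes with 100 to 1000 FPKM and 72% of those with 1000 FPKM or more were called, against 32.5% of those under 10 FPKM.

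Of the lncRNAs, TU63378 reached 69.6 ± 12.7 FPKM at 42 weeks (log2 difference from day 13 4.71 ± 0.32, adjusted p = 6.0e-06), and TU11915 rose from 0.133 ± 0.050 at day 13 to 16.0 ± 6.68 FPKM (log2 difference 3.84 ± 0.27, adjusted p = 6.0e-06). TU57895 fell from 90.7 ± 42.6 to 1.21 ± 0.59 FPKM (log2 difference -5.28 ± 0.56, adjusted p = 8.9e-05), and TU58434 fell from 117 ± 46.5 to 4.62 ± 3.77 FPKM (log2 difference -4.54 ± 0.71, adjusted p = 0.0010). In all 51 lncRNAs were higher and 123 lower, 7.9% of those tested. Of these calls 70.7% were lower as deposited, 53.6% after median scaling and 47.8% after quantile normalization, and 51 were higher and 75 lower under all 3 scalings.

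The F test over the 3 ages gave an adjusted p under the threshold for 8755 mRNAs (76.1% of those tested) and 984 lncRNAs (44.5%). Most called mRNA changes lay between day 13 and 5 weeks. On the deposited scale, a fall between day 13 and 5 weeks with no call afterwards was found for 2468 genes and a rise with no call afterwards for 594. A first call between 5 and 42 weeks was found for 497 that fell and 244 that rose. The excess of early falls depends on scaling, with 1498 rises and 1269 falls to 5 weeks after median scaling. Of the 2802 falls as deposited 1260 were called under all 3 scalings, and of the 822 rises 819. Median scaling and quantile normalization moved the median log2 difference from -0.46 to 0.014 and -0.038. Rises therefore mostly keep their calls by construction, and these shares do not compare how firm rises and falls are. Among the 790 mRNAs higher at 42 weeks than at day 13, a median of 82.3% of the log2 difference was present at 5 weeks (interquartile range 43.0 to 111.9%), and among the 3562 lower ones 74.5% (50.8 to 95.7%). For lncRNAs the median was 43.3% (14.1 to 76.9%) among the 51 higher ones and 87.5% (62.1 to 100.8%) among the 123 lower ones. The difference between these medians was not tested.

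Some transcripts were highest or lowest at the middle age. ENSGALG00000007109 had 14.6 ± 1.52 FPKM at day 13, 1378 ± 402 at 5 weeks and 12.0, 27.02 and 191 in the 42-week libraries. Its later fall of -5.02 on the log2 scale was -6.14 without the third of these and -4.19 without the first. ENSGALG00000015937 had 147 ± 27.7 FPKM at day 13, 7524 ± 3060 at 5 weeks and 930, 988 and 149 in the 42-week libraries. ENSGALG00000036956 was lowest at 5 weeks, with 264 ± 85, 11.1 ± 1.39 and 497 ± 174 FPKM at the 3 ages, as was ENSGALG00000037805, with 279 ± 34.9, 16.1 ± 3.09 and 218 ± 58.4. Among lncRNAs TU64731 was highest at 5 weeks, with 7.79 ± 2.17, 85.5 ± 37.9 and 15.1 ± 14.4 FPKM at the 3 ages, though the call of its later fall was lost in 11 alternatives, and that fall was -1.86 on the log2 scale without the third 42-week library. TU64425 was also highest at 5 weeks, at 18.2 ± 3.63 FPKM against 4.54 ± 1.07 at 42 weeks (log2 difference -1.79 ± 0.23, adjusted p = 0.0013). TU64647 was lowest at 5 weeks, with 3.11 ± 0.51, 0.485 ± 0.029 and 3.49 ± 0.84 FPKM, and so was TU61179, with 2.60 ± 0.06, 0.571 ± 0.577 and 2.94 ± 1.07 FPKM.

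In all 179 mRNAs were called highest and 204 lowest at 5 weeks, and 130 and 120 under all 3 scalings. Against the 179 and 204 of the deposited scale, independent lists would share 57.6 and 121 genes, and no such number was computed for the calls under all 3 scalings. Simulated groups with no difference between ages gave at most 0 and 1 in 100 simulations. As no gene changed in them, they cannot show how far the shared 5-week libraries raise the overlap among changed genes. Part of the excess over independent lists may come from the shared 5-week libraries, which are too few to split. The number highest at 5 weeks was 275 without the third 42-week library. For lncRNAs 18 were highest and 9 lowest, against 0.7 and 2.1 for independent lists and at most 0 in the simulations, which have the same limit.

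**Figure D4:**
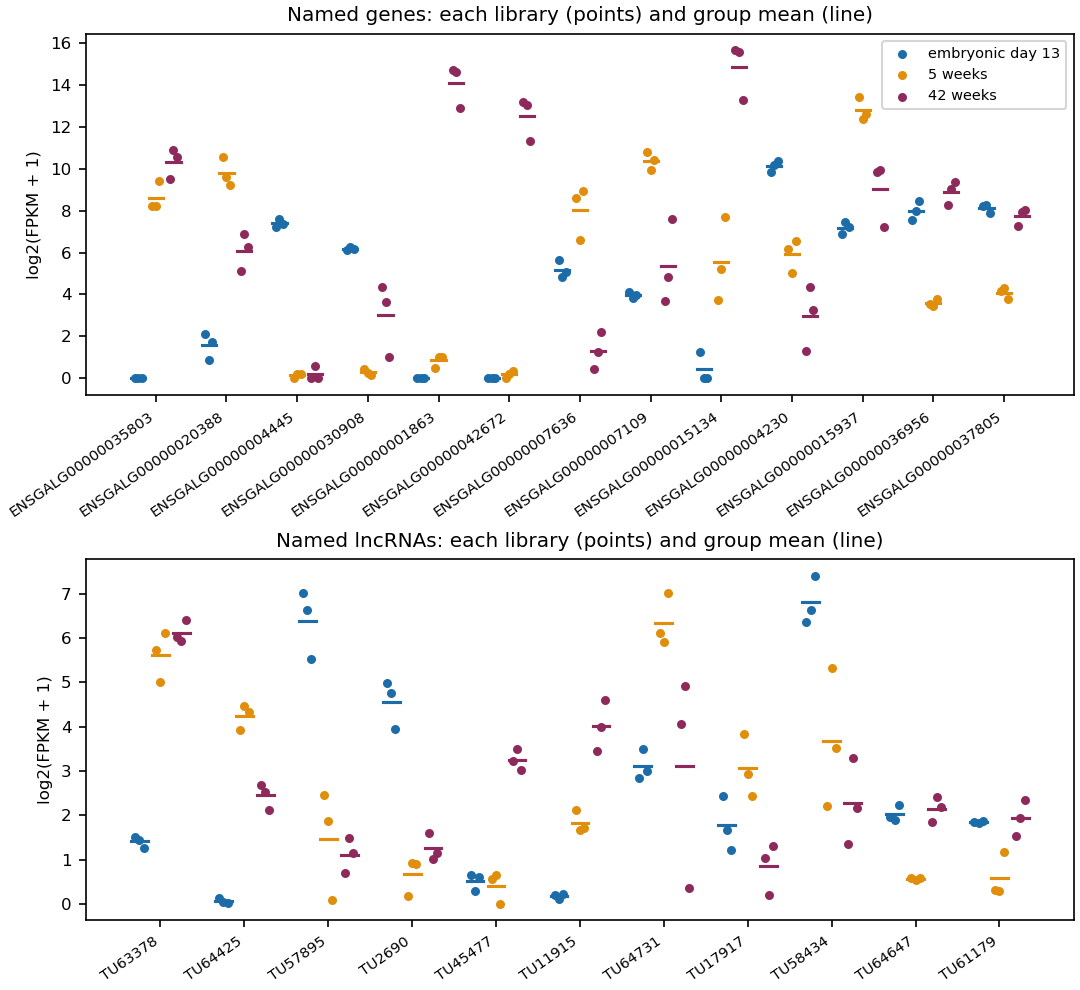
Log2(FPKM + 1) of each named mRNA (top) and lncRNA (bottom) in every library (points) with the mean of the 3 libraries of an age (line). ENSGALG00000001863, ENSGALG00000042672 and ENSGALG00000015134 are lower in the third 42-week library than in the other two of that age.

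Genes listed at 0 in all 3 libraries of an age numbered 207 at embryonic day 13, 132 at 5 weeks and 115 at 42 weeks. Of these, 16 at day 13, 0 at 5 weeks and 3 at 42 weeks had a mean of at least 10 FPKM over the other libraries. As every listed gene is above 0 in at least 5 libraries, genes present at a single age are not among them. The numbers therefore do not show how many genes are switched on or off with age.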

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

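The alternatives were planned before the data were examined, except the offset of 0.1 FPKM, which was chosen after seeing the data. In the rest of this part, pairs give features higher and lower, and the comparisons come in the order 5 weeks against day 13, 42 weeks against 5 weeks, and 42 weeks against day 13. Of the counts under alternatives, 276 stayed within 1.5 times the reported count and 60 did not. Of the named values under alternatives, 397 kept their direction and call, and 11, all of TU64731, kept their direction and lost the call, with adjusted p-values of 0.051 to 0.12. No feature called under both the reported and an alternative setting changed direction. Median scaling gave 1498 and 1269 mRNAs for 5 weeks and 1593 and 1426 for 42 weeks against day 13, and 78 lncRNAs higher in the latter. Quantile normalization gave 1270 and 1380, and 1450 and 1578 mRNAs, with 72 lncRNAs lower at 5 weeks and 83 and 76 at 42 weeks against day 13. These scalings set the medians of the ages equal by construction. With an offset of 0.1 FPKM, 781 and 1271 mRNAs were called between 5 and 42 weeks and 452 were lowest at 5 weeks, and lncRNA calls were 179 and 417, 144 and 149, and 213 and 469, with 35 highest and 56 lowest at 5 weeks, since that offset enlarges differences of low values. Without a minimum fold, mRNA calls were 1401 and 5396, 1180 and 2521, and 1273 and 6340, with 493 highest and 746 lowest at 5 weeks, and lncRNA calls 193 and 509, 136 and 140, and 233 and 571, with 58 highest and 41 lowest. The test against a 1.5-fold change gave 220 and 261 mRNAs between 5 and 42 weeks, 64 highest and 76 lowest at 5 weeks, and for lncRNAs 15 and 56, 7 and 3, and 24 and 66, with 3 highest and 1 lowest at 5 weeks. The stricter filter, which tests fewer lncRNAs, gave 24 and 76 for 5 weeks against day 13, 21 higher between 5 and 42 weeks, 26 and 81 for 42 weeks against day 13, 11 highest at 5 weeks and 209 in the F test. Leaving out each library in turn gave 604 (without 42-week replicate 1) to 1305 (without 42-week replicate 3) mRNAs lower between 5 and 42 weeks, and 141 to 275 highest at 5 weeks, the ends coming from the same libraries. Where no reason is given, the cause was not tested. The tables hold no counts, so what depth limits is unknown.

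With the replicate number as a block, 830 and 2803 mRNAs were called for 5 weeks against day 13, 499 and 815 between 5 and 42 weeks, and 801 and 3565 for 42 weeks against day 13, and no count moved by over 1.5 times. Deviations of same-numbered libraries from their age means had correlations of -0.050 to 0.145 for mRNAs and -0.028 to 0.105 for lncRNAs over 9 pairs each. Differently numbered libraries gave -0.126 to 0.081 and -0.072 to 0.084 over 18 pairs each. The highest value was of a same-numbered pair for both, but all were weak, so the numbers were not taken as a pairing. The planned gene lists and anchor genes were not run, and log2(FPKM + 1) is the deposited scale itself.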

Other observations

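The tests on the third 42-week library, all 3 tests for a mixture in it included, and the comparisons of lncRNAs and mRNAs by single level class were chosen only after the results had been seen. The tests on abundant genes, the pooled tests on lncRNA and mRNA levels and those on other splits of the libraries were set before their results. From under 1 FPKM at embryonic day 13, 9 genes reached a mean of at least 100 FPKM at 5 weeks and 21 at 42 weeks, 7 of the latter at least 1000 FPKM, with genes named for the comparisons included. In the opposite direction the numbers were 1 for 5 weeks and 2 for 42 weeks. Every listed gene is above 0 in at least 5 libraries. Genes at 0 at both later ages are therefore not listed, while genes at 0 at day 13 alone can be. For this reason the numbers of these directions cannot be compared. ENSGALG00000043533, chosen after its values were seen, had 0.123 FPKM in the third 42-week library and 1207 to 3708 FPKM in the other 8.

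The median mRNA level was lower after hatching, by a log2 shift of -0.54 at 5 weeks and -0.70 at 42 weeks against day 13 (median FPKM of the tested genes). A few abundant genes with a larger share of the fragments could lower the FPKM of all others. Dividing each library by its FPKM sum outside its 20 most abundant genes left shifts of -0.295 and -0.117, with all 3 libraries of each later age still below all 3 embryonic ones (highest 2.63 and 2.68, lowest embryonic 2.76). This argues against the 20 most abundant genes as the whole cause. The summed FPKM of a library also differed, at 543042 ± 7182 at day 13, 527079 ± 13084 at 5 weeks and 433983 ± 34518 at 42 weeks (SD, n = 3 each). The division removes that difference too, so the smaller shifts cannot be credited to the share of these genes alone. How far these genes are part of the cause stays open. Other composition effects and a difference between the ages themselves stay open.

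The third 42-week library differed from the other two of its age in 1109 genes by at least 2-fold, and after median centring still in 700, against at most 342 in any other library, which argues against scaling as the whole cause. Its lowest r with the other 42-week libraries, 0.950, was above its highest with any other age, 0.929, which argues against an exchange with another age. Of the 42-week rise over 5 weeks in the first library (111 genes) it showed a median of 27.8%, and of the fall (233 genes) 71.4%, against 90.2% and 90.8% in the second library; the 72.2% of 5-week RNA that the median rise would need keeps every fallen gene above that share of its 5-week level, yet 166 of the 233 lay below it (at most 28 in a 5-week library set against the other two) and 62 below the 35.2% that the upper quartile of the rises would need (at most 4), which argues against a mixture with 5-week RNA as the whole cause, though not as a part. Of the earlier tests, 72 genes were 2-fold above all other 8 libraries (at most 15 elsewhere), past the bound of 3 times first set, but 46 against 25 after centring, which was required only after that result, and 53.7% of its deviating genes lay outside the range of the 5-week and other 42-week libraries, past a bound of 25%, until this was changed after the result to require more than the 73.1% and 63.5% of the first and second 42-week libraries, so neither is relied on. A difference between animals was not tested and stays open, as do RNA quality and tissue sampling.

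At the same level, lncRNAs were called less often than mRNAs between day 13 and 42 weeks. The difference was 7.4 percentage points over 1 to 10 FPKM (level-stratified permutation p = 5.0e-04). By class this passed the test only at 1 to 2 FPKM (10 points, Fisher's exact test, p = 0.00028 adjusted over 3 classes). The permutation and Fisher tests of this paragraph treat features as independent, though all calls come from the same libraries. Their p-values therefore do not measure variation between birds. After median scaling the pooled difference of 2.7 points (permutation p = 0.167) averaged opposite signs. It was 8 points at 1 to 2 FPKM (Fisher's exact test, adjusted p = 0.0031). At 2 to 5 and 5 to 10 FPKM it was -6.8 and -4.5 points (Fisher's exact test, adjusted p = 0.086 and 0.47). Median scaling moves all log2(FPKM + 1) values of a library by the same amount, while that scale compresses a shared shift at low FPKM. The mRNAs of 1 to 2 FPKM can thus be moved too far. The downward shift of the mRNA table therefore stays open as a cause in all 3 classes. With mRNAs above 0 in all 9 libraries the difference was 3 points (permutation p = 0.127) and at 1 to 2 FPKM 3.9 points, no longer past the threshold (Fisher's exact test, adjusted p = 0.38), but this is stricter than the filter of the lncRNA table, since 45 of the 538 lncRNAs compared have a value under 0.1 FPKM, so the different filters of the tables stay open. The residual SD of lncRNAs was higher in 2 of the 3 level classes but not at 1 to 2 FPKM (0.243 against 0.251). In that class lncRNAs also differed by at least 1 on the log2(FPKM + 1) scale, whatever their p, less often by 9.5 points (Fisher's exact test, p = 0.00022). This argues against a larger spread between lncRNA libraries as the whole cause there. Of the features past that bound 393 of 394 mRNAs and 57 of 59 lncRNAs were called, so this count largely restates the calls. The different filters bear on it too. A difference in how lncRNAs and mRNAs change with age was not tested and stays open.

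Other splits of the libraries were fitted for each count. For the F test 100 of the 280 splits of the 9 libraries into 3 groups were drawn, the real one included. It gave 8755 mRNAs for the real ages and at most 5606 for any other, and 984 lncRNAs against at most 451. Only the real split was as large, and 1 of 100 is the smallest share this draw can give. This argues against chance at that share for both, but cannot tell age from a batch shared with it. Each pair of ages has 10 splits, too few for a share under 0.1. There the real counts were 3624, 1303 and 4352 mRNAs for 5 weeks against day 13, 42 against 5 weeks and 42 weeks against day 13, with at most 0, 3 and 0 in the other splits, and 155, 78 and 174 lncRNAs with at most 0 in each. Each of the other splits mixes both ages in each group, so the age difference enters the spread and lowers the count. Their low counts therefore do not measure the rate of false calls.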
